A study of Danio rerio with 9 samples.

How the data were processed

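Polyadenylated RNA from whole brains of adult female zebrafish was sequenced, 1 brain per library. Per the labels, the fish were of an AB and TU mix, and the knockout line was made with Cas9 and 1 guide RNA against exon 3 of fus. Per the labels' protocols, brains were dissected in ice-cold saline and stored in RNAlater, libraries were made with the strand-specific TruSeq kit, and both ends were read for 100 bases on a HiSeq2000. According to the series description, RNA was sequenced in 2 runs because of a problem with a kit lot, FUS_KO 3 was covered by the first run only and FUS_KO 1 by the second only, and the submitters treated runs as technical replicates. The submitters' processing notes name STAR 2.4.1d, featureCounts 1.4.6, DESeq2, GATK 3.5 and Picard without saying what each did. The genome build, the annotation and the strand setting of the counting are not given in the sources used here.

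The deposited gene table holds 31388 Ensembl genes with 1 column of normalized read counts per fish, a signal in which the authors had already joined the runs. In each column, 100% of the non-zero values were whole multiples of the smallest value within a tolerance of 0.01 reads, so each column is a set of whole read counts divided by 1 factor, and the reads behind it could be recovered. The authors' deposited table also gives a base mean, a log2 fold change with its standard error, a Wald score, a p-value and an adjusted p-value per gene; its column of significant genes equals an adjusted p-value under 0.1. A second deposited table, which carries the name of the IsoSCM program in its title, lists 120 sites at which read coverage along a transcript end changes. It holds, per the file headers, the coverage signal upstream of each site and site usage, taken here as the fraction of transcripts ending there. It also holds a confidence score and the difference in usage. The mutant columns are headed FUS_KD, whereas the samples column beside them reads WT and FUS_KO, so they were read as FUS_KO. In the values, the difference is WT minus FUS_KO. Each genotype has 1 value per site, so that table holds no replicates.

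Recovered reads per fish came to 34803488, 36722032, 33808654 and 36474980 for WT 1, 3, 4 and 6. FUS_KO 1, 2, 3, 5 and 6 had 17511540, 32851432, 17990278, 33571726 and 34761745. The single most abundant gene took at most 4.12% of a library. No pair of fish agreed within counting noise (the lowest chi-square per degree of freedom over genes was 14.2), so each fish was counted as 1 replicate. The reads carry no molecular identifiers, so intervals given for counts cover counting error only.

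The design fixed before the data were examined foresaw edgeR on counts, with limma-trend if the table held no counts. Since the deposited unit is a normalized count, limma-trend (limma 3.58.1, R 4.3.3) was applied to log2(normalized count + 1), FUS_KO minus WT, with Benjamini-Hochberg adjustment and a threshold of 0.05. Folds on that scale understate the change of genes with few reads. The filterByExpr function of edgeR 4.0.16, run on recovered reads, kept 20459 genes. The whole reads also went into the edgeR quasi-likelihood test with TMM factors, which called 11 genes. The design had named that test for a table of counts, and its use on recovered reads was decided after seeing the files. Whole reads also went into edgeR with RLE factors and DESeq2 1.42.0, which called 12 and 112. On counts simulated from these libraries with 200 genes changed, 20239 genes passing the filter, limma-trend found 23.9% of the genes changed by 0.5 on the log2 scale, 71.6% of those changed by 1 and 90.8% of those changed by 2, with 6 false calls. Changed genes were drawn above a minimum mean count, and each gene was simulated independently, without variation shared among fish. The shares and false calls therefore do not cover genes with few reads or the shared variation of the real libraries.

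Gene symbols and chromosomes came from the given name tables through Entrez numbers, symbols or descriptions, for the most part from RefSeq assembly GRCz12tu, which is not known to be the build of the files. Of the tested genes, 19529 had a symbol and 18164 a chromosome, 88.8%. That assembly was used for names, chromosome numbers and the order of neighbouring genes only. A check of a gene set by chromosome was held void where under 80% of the set had a chromosome. The share of a set on the chromosome of fus was compared with other tested genes by a two-sided Fisher's exact test, and shares carry exact (Clopper-Pearson) 95% intervals.

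Before the data were examined, 38 gene lists were fixed, covering pathways linked to FUS or to stress, brain cell types and neighbouring tissues. Of these, 37 had at least 5 tested members; the list of mitochondrially encoded genes matched none by name. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the lists. The rule for naming genes was also fixed beforehand: fus; called genes with a symbol that is not a placeholder, at least 1 CPM in the higher group and no overlap of groups, up to 10 per direction by fold and by p-value; up to 4 members per list by p-value; and up to 10 sites per direction of the segment table by difference in usage. A list member named in the text is among the 4 of its list with the smallest p-value unless it is said to have been chosen later.

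Alternatives fixed beforehand covered the tool, the normalization, the filter on low counts, a fold threshold, each replicate left out, the 2 shallower FUS_KO fish left out, replicate number as a block, and genes on the chromosome of fus left out. Alternatives added later were pseudocounts of 0.5 and 8, the removal of 3 fish with markers of other tissues, and other ways to count genes per chromosome. The first principal component of 10775 well-measured genes as a covariate was also added later. The edgeR test with TMM was planned for counts, and its use on recovered reads was decided later. Other splits of the 9 fish into 4 and 5 were drawn 100 times out of 126 possible, the real split included. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots. Gene length, distances in bases and the overlap of segment sites with called genes were not analysed here, since no annotation of a stated build was given.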

Results

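Brains of 4 wild-type (WT) and 5 fus knockout (FUS_KO) adult female zebrafish were profiled by RNA sequencing. FUS is an RNA-binding protein of the FET family whose human gene is mutated in some forms of amyotrophic lateral sclerosis, and the comparison asks which transcripts differ when it is lost from a whole vertebrate brain. WT libraries held 33808654 to 36722032 reads in genes. FUS_KO 2, 5 and 6 held 32851432 to 34761745, whereas FUS_KO 1 and FUS_KO 3, each sequenced in a single run, held 17511540 and 17990278. The first principal component of well-expressed genes took 37.9% of the variance. It placed WT 1, 3 and 4 and FUS_KO 3 on one side (scores of -25.1 to -10.9) and WT 6 with FUS_KO 1, 2, 5 and 6 on the other (8.97 to 16.5), so the libraries did not separate by genotype alone.

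The targeted gene fus (ENSDARG00000037968) fell in every mutant fish. Its level was 8168 ± 225 normalized read counts in WT (SD, n = 4) and 3648 ± 191 in FUS_KO (SD, n = 5), or 44.7% of WT. WT fish ranged from 7939 to 8423 and mutants from 3433 to 3949, with no overlap. The log2 fold change was -1.16 with a standard error of 0.056 (limma-trend adjusted p = 1.78e-05; two-sided exact permutation p = 0.00794 over 126 splits, the smallest this design can give). Transcripts of the locus therefore remained at a reduced level, and gene-level counts do not show whether protein was made.

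Among 20459 genes tested, 11 passed an adjusted p of 0.05, of which 3 were higher and 8 lower in FUS_KO. The higher named genes were atf4b, a transcription factor gene of the amino acid and stress response, and flii, which encodes an actin-remodelling gelsolin-family protein. Levels of atf4b rose from 9737 ± 855 to 17339 ± 1672 normalized counts, or 178% of WT (log2 0.83, SE 0.086, limma-trend adjusted p = 0.00654), and those of flii from 2629 ± 394 to 4070 ± 68.6 (log2 0.64, SE 0.087, adjusted p = 0.0363). The lower ones besides fus were coa3b, a gene for an assembly factor of cytochrome c oxidase, and tmprss15, the gene for the protease enteropeptidase. Expression of coa3b fell from 379 ± 143 to 58.6 ± 8.19 normalized counts, 15.5% of WT (log2 -2.60, SE 0.23, adjusted p = 0.00394). Expression of tmprss15 fell from 831 ± 248 to 273 ± 23.7, 32.9% of WT (log2 -1.55, SE 0.18, adjusted p = 0.0113). All of these had n = 4 WT and n = 5 FUS_KO fish and no overlap between groups by the exact counts. At an unadjusted p under 0.05, 1194 genes differed, 668 of them higher, where about 1023 are expected by chance, and without 1 fish the number ran from 811 (without WT 4) to 2760 (without FUS_KO 3). The count of calls depended on the tool and on single fish: DESeq2 on the recovered reads called 112 genes (77 higher, 35 lower), including all 11, and without WT 6 limma-trend called 117. With the first principal component as a covariate, 2 genes were called, fus and atf4b.

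**Figure D1:**
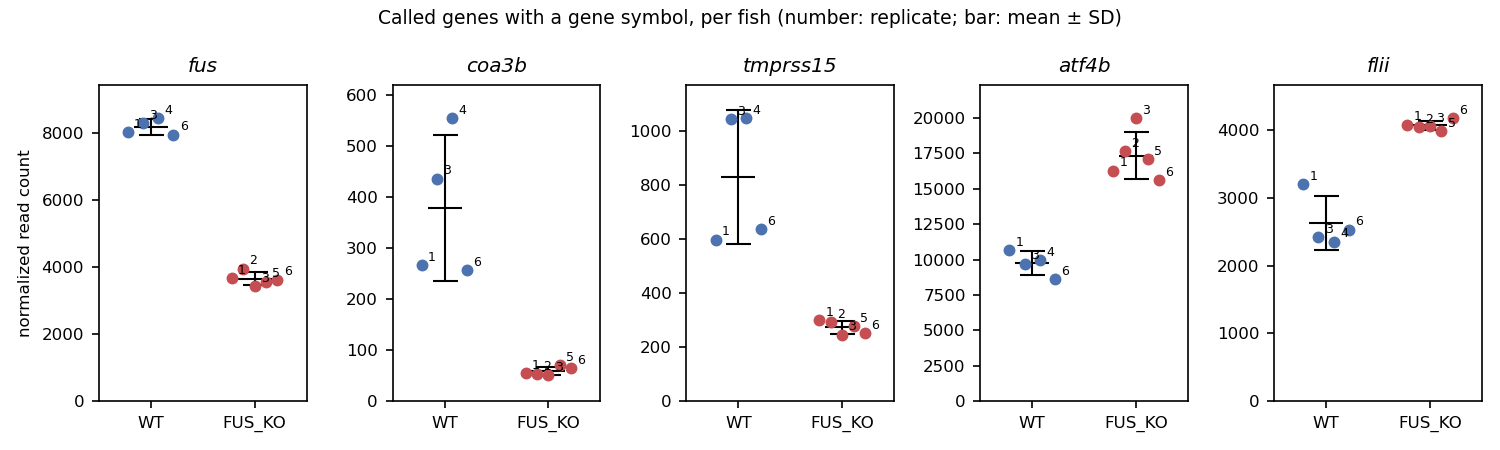
Normalized read counts (vertical axes, from 0) of the called genes with a gene symbol, for each WT (blue) and FUS_KO (red) fish; numbers give the replicate and bars the mean ± SD. Mutants lie below every WT fish for fus, coa3b and tmprss15 and above every WT fish for atf4b and flii.

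The other 6 called genes carry placeholder names and were singled out after their values were seen. A gene with no symbol, ENSDARG00000078024, fell from 89.1 ± 22.9 to 1.5 ± 1.71 normalized counts (limma-trend adjusted p = 0.00431), and si:ch211-134c9.2 from 26.0 ± 13.0 to 0.346 ± 0.475 (adjusted p = 0.00924). Levels of zgc:195170 fell from 73.0 ± 18.2 to 7.54 ± 3.03 (adjusted p = 0.00924) and those of si:dkeyp-55h4.2 from 24.9 ± 3.38 to 2.54 ± 1.67 (adjusted p = 0.0331). The gene si:dkey-66i24.9 fell to 34.3% of WT (adjusted p = 0.00431), whereas ENSDARG00000105252 rose to 241% (adjusted p = 0.025). A pair of genes, cirbpb and rbm11, lay just outside the limma-trend threshold, with adjusted p-values between 0.05 and 0.1. DESeq2 called both (adjusted p = 6.99e-11 and 9.21e-07), and edgeR with TMM factors neither (adjusted p = 0.0878 and 0.0597). The abundant cirbpb, which encodes a cold-inducible RNA-binding protein, was at 57959 ± 1771 normalized counts in WT and 44098 ± 2076 in FUS_KO (76.1% of WT, limma-trend adjusted p = 0.0787). The RNA-binding protein gene rbm11 was at 48.4% of WT (log2 -1.03, adjusted p = 0.0544) and lies next to tmprss15 among the tested genes of chromosome 21 in assembly GRCz12tu. Leaving out 1 fish at a time ended the call of flii in 7 of the 9 refits, of si:dkeyp-55h4.2 in 6, of ENSDARG00000105252 in 5, of tmprss15, zgc:195170 and si:ch211-134c9.2 in 2 each and of atf4b in 1 (adjusted p = 0.0503), with the fold of flii between 0.59 and 0.74 and that of tmprss15 between -1.70 and -1.43 on the log2 scale.

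Knockout and wild-type fish of an outbred cross can differ in the chromosome segment that carries a mutation, so the positions of changed genes were compared with that of fus, which lies on chromosome 3 of assembly GRCz12tu. The named genes atf4b, flii and coa3b and the placeholder gene si:dkey-66i24.9 lie on the same chromosome. Of the 11 called genes, 7 could be placed and 5 of these, fus included, were on chromosome 3; as only 63.6% of the set had a position, a test on it is void. Among 287 placed genes with an unadjusted p under 0.01, a set chosen after the data were seen, 80 (27.9%) lay on chromosome 3, against 4.76% of other tested genes (odds ratio 7.73, two-sided Fisher's exact p = 3.28e-37). Fisher's test treats genes as independent, which genes measured in the same fish are not, so its p-values here overstate the evidence. Among 100 splits of the fish, 2 reached that share, the real one included. With 1 fish left out, the share ran from 16.5% (without FUS_KO 3, odds ratio 3.96) to 38.7% (without WT 1, odds ratio 12.7). Of the 80, 49 were higher and 31 lower in FUS_KO. The number on chromosome 3 ran from 40 (without WT 4) to 94 (without FUS_KO 3) with 1 fish left out. DESeq2 calls gave 28 of 92 placed genes, 30.4% (Fisher's exact p = 6.95e-15). Seen by chromosome, 8.59% of 931 tested genes of chromosome 3 had a p under 0.01 (exact 95% interval 6.87 to 10.6), against 1.2% of genes elsewhere. Next came chromosome 21 with 2.98% (Fisher's exact p = 0.005, adjusted p = 0.0625 over 25 chromosomes) and chromosome 22 with 2.66% (adjusted p = 0.217). In gene order along chromosome 3, the share was 8% within 100 tested genes of fus on either side, 14% from 101 to 200, 10% from 201 to 300 and 4.55% from 301 to 517.

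**Figure D2:**
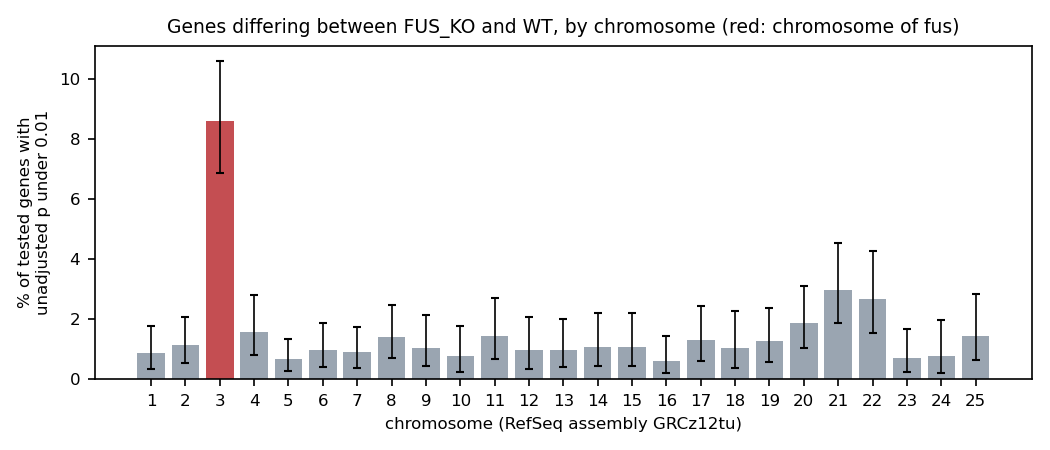
Percent of tested genes with an unadjusted p under 0.01 between FUS_KO and WT (vertical axis) on each chromosome of assembly GRCz12tu (horizontal axis), with exact 95% intervals as error bars. Chromosome 3, which holds fus (red), reached 8.59% and the next, chromosome 21, 2.98%.

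Genes of photoreceptors and of the pineal gland formed the gene list with the largest shift. Of 43 tested members, none passed over all genes by limma-trend (28 had an unadjusted p under 0.05), 5 were called by DESeq2, and 26 were higher in FUS_KO when adjusted over the list alone, with a list median of 2.78 on the log2 scale (camera adjusted p = 4.48e-27; adjusted p = 0.459 with an estimated correlation). Examples were pde6ha, a cone phosphodiesterase subunit gene (84.8 ± 91.7 in WT and 787 ± 374 normalized counts in FUS_KO), gngt2a, a cone transducin subunit gene on chromosome 3 (39.7 ± 70.5 and 628 ± 483), and rcvrn2, a recoverin gene (70 ± 119 and 522 ± 263). The WT spread came from 1 fish. The list medians per fish, relative to the mean of all fish, were -2.03, -2.39 and -2.85 in WT 1, 3 and 4 but 0.98 in WT 6, and 0.97, 1.4, 1.47, 2.18 and 0.93 in FUS_KO 1, 2, 3, 5 and 6. Between groups the medians differed with an exact permutation p of 0.0238 (adjusted p = 0.294 over 37 lists). The smallest p this permutation test can give is 0.00794, so no single list could pass after adjustment over 37 lists. The adjusted value therefore does not weigh against the list. Markers of other tissues stood out in single fish of both genotypes, with a median of 1.64 for skeletal muscle in FUS_KO 2, of 1.03 and 0.865 for skin and epithelium in FUS_KO 5 and WT 1, and of 0.741 for pituitary in WT 6. Neither the muscle nor the skin list differed by genotype (camera adjusted p = 0.585 and 0.542).

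Immediate early genes, which neurons switch on within minutes of activity, were lower in FUS_KO. Of 35 members, 30 had a lower mean; none passed over all genes by limma-trend (10 had an unadjusted p under 0.05), 3 were called by DESeq2 and 7 passed when adjusted over the list alone, all lower (median -0.34; camera adjusted p = 7.15e-08; adjusted p = 0.459 with an estimated correlation). The neuronal transcription factor gene npas4a was at 20399 ± 4803 normalized counts in WT and 11052 ± 2968 in FUS_KO, 54.2% of WT. The growth-arrest gene btg2 was at 70.7% of WT and the AP-1 gene jund fell from 8055 ± 635 to 5658 ± 886. Fish medians ran from 0.11 to 0.28 in WT and from -0.35 to 0.05 in FUS_KO, lower in every mutant than in every WT fish (exact permutation p = 0.0238, adjusted p = 0.294 over 37 lists). As with retina and pineal genes, a single list could not pass after that adjustment in this design.

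**Figure D3:**
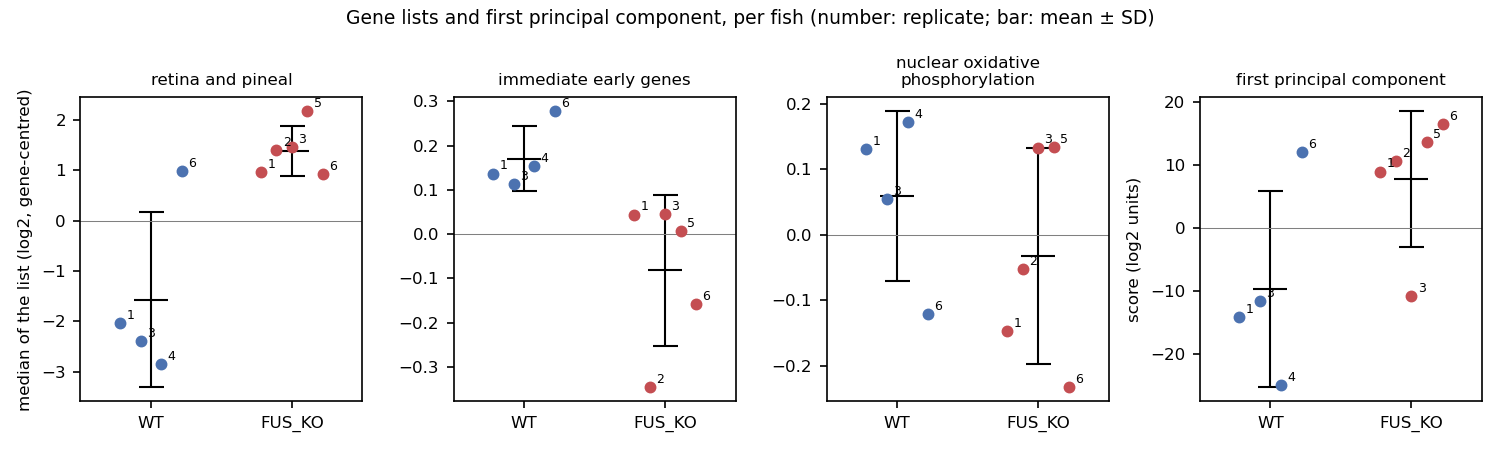
Per fish (WT blue, FUS_KO red, number for the replicate, bar for mean ± SD), the median over a gene list of log2 values centred on each gene's mean, for 3 lists, and at the right the score on the first principal component. WT 6 lies with the mutants for retina and pineal genes (0.98) and on the component, whereas immediate early genes are lower in every mutant than in every WT fish.

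Several other lists shifted by under 0.25 on the log2 scale. Genes for nuclear subunits of oxidative phosphorylation had a median of -0.088, with 79 of 94 members lower (camera adjusted p = 2.11e-05), and ribosomal protein genes of -0.091, with 82 of 92 lower (adjusted p = 5.31e-05; 0.0558 without FUS_KO 1 and FUS_KO 3). The latter list was matched by name and takes in rps19bp1, which is not a ribosomal protein gene. Hypothalamic neuropeptide genes had a median of -0.14, with 49 of 58 lower (adjusted p = 5.31e-05), and genes of FET proteins and their RNA-binding partners of -0.078, with 29 of 35 lower (adjusted p = 0.000242). Cholesterol synthesis genes (median -0.18, adjusted p = 0.00181) and p53 and DNA damage genes (-0.084, adjusted p = 0.0426) were also lower by camera, while lymphocyte and neutrophil genes (0.21, adjusted p = 0.0223) and genes of meninges and extracellular matrix (0.21, adjusted p = 0.0226) were higher. These 4 calls depended on single fish: with 1 left out, that of p53 was lost in 4 of 9 refits (adjusted p up to 0.219), that of lymphocytes and neutrophils in 4 (up to 0.289), that of cholesterol synthesis in 3 (up to 0.108) and that of meninges in 3. The last was not called without FUS_KO 5 (adjusted p = 0.746), whose median was 0.703 against -0.24 to 0.136 in the other mutants. With an estimated correlation each of these 8 lists had an adjusted p of 0.753. Adjusted over the list alone, only rps11b and rpl27 among ribosomal proteins and ndufs8b among oxidative phosphorylation genes passed, and none in the other 6 lists. The copies rps11b (60.7 ± 78.1 in WT, 288 ± 29.3 in FUS_KO) and ndufs8b (1.02 ± 1.5 and 16.2 ± 6.93) were higher, against their lists. In the gene table ndufs8b is annotated as a polymorphic pseudogene. Its mean was 0.557 CPM in the higher group, so its rise rests on few reads. In WT, rps11b was at 178 normalized counts in WT 1 and at most 26.0 in the other fish, and without WT 1 it was called over all genes (adjusted p = 1.98e-05). The gene rpl27, on chromosome 3, was at 72.1% of WT. The FUS relative ewsr1a was at 85.4% of WT and the splicing factor gene sfpq at 84.4% (limma-trend adjusted p = 0.361 and 0.479, DESeq2 adjusted p = 0.0212 and 0.16). DESeq2 called 1 member in each of the FET, ribosomal and oxidative phosphorylation lists and 0 in each of the others. In contrast, tnpo2a, a transportin gene on chromosome 3, was at 120%. The satiety peptide gene ccka was at 76.8% and the granin gene scg2b at 86.8% of WT. In the remaining lists hmgcrb was at 85.9%, gadd45bb at 71.7%, il7r at 149% and ogna at 200% of WT, none of which passed over all genes; the log2 fold of ogna was 0.79, and 0.48 without FUS_KO 5.

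By camera, no shift passed the threshold for the remaining 27 lists. The adjusted p-values were 0.686 for pan-neuronal, 0.701 for glutamatergic and 0.701 for GABAergic genes, with medians of -0.025, -0.011 and -0.095. Those of radial glia and astroglia (0.358), oligodendrocytes (0.358), microglia and macrophages (0.29), and interferon response (0.302) were also above it. Orthologs of genes mutated in amyotrophic lateral sclerosis had a median of -0.039 and a mean of 0.014 (adjusted p = 0.517), and synaptic genes with long introns a median of 0.055 (adjusted p = 0.165). The unfolded protein and amino acid response list, which holds atf4b, had a median of -0.056 (adjusted p = 0.166), but was called by fry in either direction (adjusted p = 0.0113), and atf4b alone passed when adjusted over the list alone. Heat shock (0.232), autophagy and lysosome (0.679), cleavage and polyadenylation (0.701) and minor spliceosome and U7 genes (0.302) showed no call either.

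The authors' deposited table flags 115 genes at an adjusted p under 0.1, 65 higher and 50 lower in FUS_KO, and 74 at under 0.05. All 11 genes called here are among those 74 in the authors' deposited table, in the same direction. Across 20459 genes, which are not independent replicates, both sets of log2 fold changes had a Spearman correlation of 0.952. The same libraries underlie both, so this compares processing only. In the authors' deposited table the fold of cirbpb is -0.38 on the log2 scale, against -0.39 by DESeq2 here. Those of coa3b and ENSDARG00000078024, with fewer reads, are -1.47 and -1.59, against -2.68 and -5.91. The gap was not limited to genes with few reads. For npas4a the folds are -0.58 against -0.88, and for gngt2a, which varied widely among fish, 0.13 against 3.99. Sizes of folds should therefore not be compared between the tables.

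Changes along transcript ends were taken from the authors' deposited table of 120 sites at 109 loci, where usage of a site differed by at least 0.2 between genotypes. It covers 1 value per genotype and no replicates, so no test between genotypes was possible and the values are descriptions. Usage was higher in FUS_KO at 69 sites (57.5%, exact 95% interval 48.1 to 66.5) and higher in WT at 51, with a median absolute difference of 0.261. At a difference of 0.3 or more the direction turned, with 24 sites higher in FUS_KO and 26 in WT (48.0%). Coordinates are given as in that table, whose build is not stated. The largest difference towards WT lay on chromosome 2 at position 10182593 (usage 0.956 in WT, 0.00 in FUS_KO): upstream coverage was 12.9 and 43.6. The adjacent site at 10182093 had the largest difference towards FUS_KO (0.00 and 0.895), with an upstream coverage of 0.56 in WT and 48.6 in FUS_KO, so that in WT the 500-base segment between them was nearly uncovered. Other large differences towards WT were on chromosome 23 at 36765051 (0.889 and 0.00) and chromosome 3 at 30009433 (0.81 and 0.00). Towards FUS_KO they were on chromosome 3 at 30949544 (0.00 and 0.892) and chromosome 2 at 54861164 (0.0808 and 0.873). Upstream coverage at these sites was 2.25 and 5.77 in WT, against 30.75 and 36.8 in FUS_KO, so their WT usage rests on little coverage. By chromosome, 26 of the 109 loci (23.9%, exact 95% interval 16.2 to 33.0) lay on chromosome 3, which holds 5.13% of the placed tested genes in assembly GRCz12tu. Chromosomes 15, 21 and 22 had 11 loci each.

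**Figure D4:**
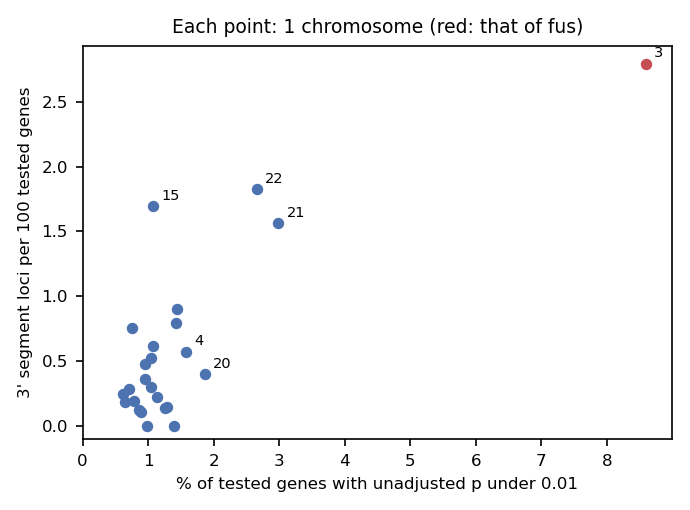
For each chromosome (points), loci in the authors' deposited segment table per 100 tested genes (vertical axis) against the percent of tested genes with an unadjusted p under 0.01 (horizontal axis). Chromosome 3 (red) is highest on both axes, with 2.79 loci per 100 genes and 8.59%.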

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

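Refits without 1 fish, the main test of gene lists and that with an estimated correlation were planned. Tests of a chromosome copy change and of other splits, and that of lists without the shallower fish, were added after seeing the data but before their own values. All others here, that of the principal component included, were chosen after results had been seen.

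Changed genes gathered on the chromosome of fus. The share of genes with p under 0.01 was 8.59% there, with a lower bound of 6.87%, above the upper bound of every other chromosome (at most 4.52%). The 80 genes behind it became 40 without WT 4 and 94 without FUS_KO 3, so this percent depends on single fish. Of the 100 splits drawn, 2 reached the real share of the placed genes (27.9%), the real one included. The other had 29.2% of a smaller set, and the next highest 23.1%. Chance assignment of fish is therefore unlikely for this excess but not excluded, as the set was chosen after the data were seen. An effect of FUS loss that ignores position is at odds with the odds ratio of 7.73 (3.96 to 12.7 with 1 fish left out), and an added or lost chromosome copy with a median log2 fold change of 0.0104 (bootstrap bounds -0.00778 to 0.0297). A candidate explanation is an AB or TU haplotype that travelled with the mutation and carries its own expression levels and transcript ends, which may include coa3b, flii and atf4b. Whether reads from that haplotype also align differently stays open, since no reads were used. A response to FUS loss of single genes on chromosome 3 stays open too.

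Photoreceptor and pineal genes were higher in mutants and in WT 6. Their members moved together among fish of the same genotype, with a mean pairwise correlation of 0.421, above the 95th percentile of random lists of like expression (0.0742). Pineal or retinal tissue left on some brains may give this. Some other lists moved together more, such as ribosomal proteins (0.558) and cholesterol synthesis (0.516), and others less. The value alone therefore cannot tell left tissue from other reasons for members to move together. Single genes point to more than 1 source: aanat2, a melatonin synthesis gene of the pineal gland that lies on chromosome 3, was at 524 normalized counts in WT 6 and at 3.71 to 24.1 in the other WT fish, and reached 561 to 1121 in all 5 mutants, whereas rho, the rod opsin gene, reached 13940 in FUS_KO 2 and 14618 in FUS_KO 5 and at most 36.6 in any other fish (both genes chosen after their values were seen). An effect of genotype cannot be told apart from dissection here, because 1 WT fish of 4 had the level of the mutants (exact permutation p = 0.0238). Without WT 6, 21 of the 117 called genes were on this list.

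The lower gene lists fall into separate kinds. With the first principal component as a covariate, the median of oxidative phosphorylation genes changed sign (-38.0% of its size) and that of ribosomal proteins kept 36.5%, so the axis that sets WT 1, 3 and 4 and FUS_KO 3 against the other fish may account for both shifts. The median of the FET list kept 6.73% (adjusted p = 0.378) and that of hypothalamic neuropeptides 38.1% (adjusted p = 0.672), so the same may hold for them, while p53 and DNA damage genes kept 56.4% (adjusted p = 0.357) and cholesterol synthesis genes 75.9% (adjusted p = 0.0501). Oxidative phosphorylation genes were then called in the other direction (adjusted p = 0.0104), and counting this as a loss of the shift was decided after that value was seen. The component was computed from the same fish and overlaps with genotype. The median of immediate early genes kept 101.4% and stayed called (camera adjusted p = 6.92e-05), although the folds of npas4a, btg2 and jund shrank to -0.67, -0.35 and -0.37, and without the covariate the list was not called with an estimated correlation (adjusted p = 0.459). The median was -0.36 without the shallower FUS_KO 1 and FUS_KO 3, which argues against depth as its source, as the kept median does against the axis as the source of the whole shift. Handling of the brains before storage may lower such genes as FUS loss might: members moved together within genotypes (mean correlation 0.14, random 95th percentile 0.0731), and no value here separates these explanations. FUS loss stays open, as every mutant lay below every WT fish (exact permutation p = 0.0238). For the number of lists called, 10, chance assignment cannot be excluded: 63 of 100 splits called as many, up to 17.

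A total of 158 groups of 4 or 5 fish were searched for 1 fish far from the rest, and 19 stood out. Chance gives about 1 in 20 only for independent groups of normally distributed values. Many genes here were chosen by p-value or after their values were seen, and some share a list. The number that stood out can therefore not be weighed against that rate. In WT 6 the values that stood out were pde6ha (221 normalized counts, others 24.9 to 56.3), gngt2a (145, others 2.49 to 8.04), rcvrn2 (249, others 6.50 to 14.3), aanat2 (524), cirbpb (55323, others 58552 to 59064), ogna (38.9, others 28.6 to 29.0) and the histone list (median -0.177, others 0.138 to 0.155). In WT 1 they were ENSDARG00000105252 (53.6, others 41.5 to 42.1), tnpo2a (3482, others 3019 to 3063), gadd45bb (233, others 315 to 325) and rps11b (178, others 17.5 to 26.0). WT 4 stood apart for the lists of axon growth and regeneration (-0.0116, others 0.0432 to 0.0543) and of neurons (-0.0245, others 0.0301 to 0.0407). Among mutants, FUS_KO 5 stood apart for rps29 (74.3, others 42.1 to 50.9) and skin and epithelium (1.03, others -0.474 to -0.0667), FUS_KO 2 for skeletal muscle (1.64, others -0.534 to 0.0748), FUS_KO 3 for hypothalamic neuropeptides (0.101, others -0.112 to -0.0571) and radial glia and astroglia (0.158, others -0.0614 to -0.0223), and FUS_KO 6 for the circadian clock list (0.18, others -0.0571 to -0.003).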

How the results depend on the processing

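Results for pseudocounts, fish with markers of other tissue and the 6 fish without a block were added after seeing the data. So were those for gene lists without FUS_KO 1 and FUS_KO 3, the principal component, unplaced genes and p under 0.01. The edgeR test with TMM factors was planned for counts, and its use on recovered reads was decided after seeing the files. The fold of fus stayed between -1.19 and -1.14 with each fish left out and was called in each of those fits, under DESeq2, with RLE factors, either pseudocount and the principal component, but not with the replicate block. Called genes numbered 9 to 12 under edgeR (TMM 11, RLE 12), without a filter (11), with a stricter filter (9), with a log2 fold of at least 1 (9), with either pseudocount (10 and 11) and without FUS_KO 1 and FUS_KO 3 (9, of which 6 shared). They numbered 112 under DESeq2, 5 without the chromosome of fus (5 of the 11 lie there, and 1 more lost its call on readjusting over the remaining genes), 97 without WT 6, FUS_KO 2 and FUS_KO 5 (25 of them on the retina and pineal list), 2 with the principal component as covariate, and 4 to 117 with 1 fish left out. The low end was without WT 3 (4) and WT 4 (5), and the high end without WT 6 (117) or WT 1 (18); all 11 genes kept their direction. Except where genes or fish were removed, the cause was not tested.

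Replicate numbers 1, 3 and 6 occur in both genotypes. Deviations of same-numbered fish correlated at -0.00757, 0.255 and 0.213. Correlations of differently numbered fish were not computed for comparison, so whether the numbers pair fish stays open. A fit with the replicate block over these 6 fish called 0 genes (1030 at an unadjusted p under 0.05), against 1 for the same 6 fish without it; fus was at -1.18 (limma-trend adjusted p = 0.0568), and 15 lists were called, without those of lymphocytes and neutrophils (adjusted p = 0.353) and of p53 and DNA damage (0.0517) and with the meninges and extracellular matrix list lower in place of higher (adjusted p = 0.00311). With 6 fish, few residual degrees of freedom remain.

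Lists called numbered 8 to 13 with 1 fish left out, 8 without FUS_KO 1 and FUS_KO 3, and 10 with RLE factors or other pseudocounts. With the principal component 7 were called, of which 4 are among the 10: retina and pineal, immediate early, lymphocyte and neutrophil genes, and oxidative phosphorylation, now higher (adjusted p = 0.0104). The FET, neuropeptide, ribosomal, cholesterol, meninges and p53 lists lost their call. None was called with an estimated correlation (0) or by fry (0). In either direction, fry called 1, the unfolded protein and amino acid response (adjusted p = 0.0113). Retina and pineal, immediate early, FET, neuropeptide, ribosomal and oxidative phosphorylation lists kept their call in all 9 refits without 1 fish. Of placed called genes, the percent on chromosome 3 ran from 15.1 (without WT 6) to 100 with 1 fish left out. All but 1 of these refits (without WT 4, 4 of 5 genes placed), and the sets at an adjusted p under 0.01 and 0.1, had under 80% of genes placed and are void as support, whereas DESeq2 calls (30.4%) and genes with p under 0.01 (27.9%) were not. All genes called here at adjusted p under 0.05, 0.1 and 0.01 were also called in the authors' deposited table (11, 13 and 7), which called 73, 114 and 43 of the tested genes. The share of segment sites higher in FUS_KO was 60.6% with 1 site per locus, 48.0% at a difference of 0.3 or more (26 sites higher in WT, 24 in FUS_KO, so its direction rests on small differences) and 51.7% at coverage of at least the median. Over 592 values for 40 single genes, 0 changed direction, 45 lost a call and 20 gained one. These genes were chosen for small p-values in the same fish or after their values were seen, and the fits share most fish. Few changes of direction could therefore occur, and their absence is no sign of robustness.

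Fits per run were not made, since runs are joined in the table; gene length and windows in Mb were not run for want of a stated build, nor was the overlap of segment sites with called genes. Small changes can be missed with these libraries: in the simulation 23.9% of genes changed by 0.5 on the log2 scale were found.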

Other observations

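Tests in this part were chosen after the result was seen, except that of gene order on chromosome 21 and that of other splits.

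Chromosomes with many changed genes also had many loci in the segment table. Over 25 chromosomes, loci per 100 tested genes and the percent of genes with p under 0.01 had a Pearson r of 0.80 (permutation p = 0.00016) and a Spearman rho of 0.487 (permutation p = 0.0149). Without chromosome 3 they were 0.655 (permutation p = 0.00263) and 0.42 (p = 0.0415), and without chromosomes 3 and 21, which lie farthest from the median, 0.547 (p = 0.015) and 0.352 (p = 0.1). This is consistent with linked sequence differences that alter both levels and transcript ends, as a hypothesis; the build of the segment table is not known to be that used for gene positions.

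The adjacent genes tmprss15 and rbm11 on chromosome 21 raise the question of a further linked segment there. Neighbouring genes with p under 0.01 on that chromosome lay a median of 22.5 tested genes apart, against 23 for random placings (permutation p = 0.47, adjusted p = 0.47 over 3 chromosomes), so no clustering along the chromosome was detected with 21 such genes. On chromosome 3 itself the median gap was 7 against 8 (permutation p = 0.224). The gap test thus found no clustering even where such genes were in excess, so it cannot decide on a linked segment on chromosome 21.

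For the count of called genes, chance assignment of fish cannot be excluded: 6 of the 100 splits, the real one included, called at least 11 genes, and the highest other split called 3007. That split sets WT 1, 3 and 4 and FUS_KO 3 against WT 6 and FUS_KO 1, 2, 5 and 6, the same division as the first principal component, and points to a structure of the samples that the labels do not name. It differs from the real split only in WT 6 and FUS_KO 3. The level of fus matched the label in both, at 7939 and 3433 normalized counts, so an exchange of these fish does not account for it.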
